A study of Mus musculus with 12 samples.

How the data were processed

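RNA from 12 subcutaneous C26 tumours, 4 per treatment group (PBS, Dox and CP-Dox), was measured on Affymetrix mouse expression arrays, 1 array per tumour. Per the labels' protocols, tumours were collected 48 h after treatment into an RNA preservative, total RNA was purified on columns, and biotinylated cRNA was prepared from it. The deposited values are log2 signals made by the authors with RMA, which corrects background, normalizes between arrays by quantiles and summarizes probes into probe sets, and Partek is also named in the submitters' processing notes. The versions of RMA and Partek and the order of the steps were not given in the sources used here. The values were used without further normalization. Sample groups came from the sample titles, whose replicate numbers name separate mice.

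The table held 22690 probe sets. Control probe sets (64) were left out, as were 691 probe sets with several gene symbols and 1555 with none. The 20380 probe sets with 1 symbol stood for 12393 genes, and where a gene had more than 1 probe set (4956 genes) the one with the highest mean over the 12 arrays was kept. Gene identifiers of 20351 probe sets were found in the reference table, and 0 symbols changed.

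The 3 comparisons (CP-Dox against PBS, Dox against PBS, and CP-Dox against Dox) were contrasts of 1 linear model with a mean per group, fitted over all 12 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. P values are two-sided and were adjusted by Benjamini and Hochberg over the 12393 genes of a comparison, and rose, fell and changed are used for an adjusted p under 0.05. No minimum signal and no minimum fold change was applied. Fixed lists of genes, 18 of pathways and 13 of cell type markers, were tested with camera from limma at a preset inter-gene correlation of 0.01 and with an estimated correlation, adjusted over the 31 lists. Of 627 genes in the lists, 552 were measured, and Thy1 and Top2a stand in 2 lists each. The mean of a list in an array was expressed relative to the mean of the PBS arrays. The expected overlap of the responses came from 100 simulated draws with no effect and the same PBS arrays, and from splits of the PBS arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

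The model, the lists, the tests, the alternatives and the rule for naming genes were chosen before the data were examined, apart from choices named as later ones. By that rule, named genes are the 8 largest rises and 8 largest falls among genes past the threshold whose groups do not overlap, or the 5 with the lowest p where none passed, up to 4 members with the lowest p of each list described, and a set of always reported genes: Cdkn1a, Mdm2, Ccng1, Top2a, Mki67, Txnip, Abcb1a, Abcb1b and Ccnb1, which had no probe set with a single symbol. The alternatives were another round of quantile normalization, centring on medians, a filter on the dimmest 40% of genes, other treatments of probe sets, other variance models, array weights, a fit of the compared groups alone, the replicate number as a block, stricter thresholds, and leaving out each array in turn. Covariates for muscle and skin markers, the list counts without CP-Dox replicate 2, and lists of serine and one-carbon and of erythroid precursor genes were added after the data were seen. Leaving out an array that lies apart from its group tends to lower the spread and to favour calls. The list counts without CP-Dox replicate 2 are therefore not separate support.

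Tested on simulated data with the same design, 100 genes per fold size changed among 12393, the limma fit recovered 79%, 78% and 76% of 2-fold changes in the 3 comparisons, in the order given above, and 53%, 55% and 47% of the smaller ones, with 0 called in the wrong direction. In each of the 3 runs, 8 unchanged genes were called. The simulated genes were independent and had the same spread in every group, so that these shares may not hold for the real arrays. The number of arrays limits the precision.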

Results

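Gene expression was measured in subcutaneous tumours of C26, a mouse colon carcinoma line grown in Balb/c mice, 48 h after a treatment given on day 8 after inoculation, when the tumours measured about 50 mm3. The mice received free doxorubicin (Dox), a chemotherapy drug that intercalates into DNA and traps topoisomerase II, or CP-Dox, the same drug attached to a chimeric polypeptide carrier, or phosphate-buffered saline (PBS). Each group held 4 mice, and each tumour was hybridized to its own short-oligonucleotide expression array, which gave 12 arrays. The values are RMA signals on a log2 scale, so that a difference of 1 is a 2-fold change. The dose was not given in the sources used here. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.13. Unless another error is named, log2 fold changes are given ± the standard error of the limma fit, with n = 4 tumours per group.

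The groups did not separate fully along the main axes of variation. The first 3 principal components held 39.98%, 17.3% and 15.8% of the variance, and CP-Dox replicates 1, 3 and 4 lay apart from all PBS and Dox arrays on component 1, whereas CP-Dox replicate 2 lay at the opposite end. CP-Dox replicate 2 had a mean correlation of 0.948 with the other CP-Dox arrays, compared with 0.971 to 0.977 for those 3 arrays and 0.981 to 0.990 within the PBS and Dox groups. Markers of neighbouring tissue also varied between tumours. The mean of 14 keratinocyte and skin markers exceeded the PBS mean by 2.69 and 3.89 on the log2 scale in CP-Dox replicates 1 and 3, and by at most 0.09 in each of the other arrays. Skeletal muscle markers were high in PBS replicates 3 and 4, Dox replicate 2 and CP-Dox replicates 3 and 4, intermediate in CP-Dox replicates 1 and 2, and low in PBS replicates 1 and 2 and Dox replicates 1, 3 and 4.

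**Figure D1:**
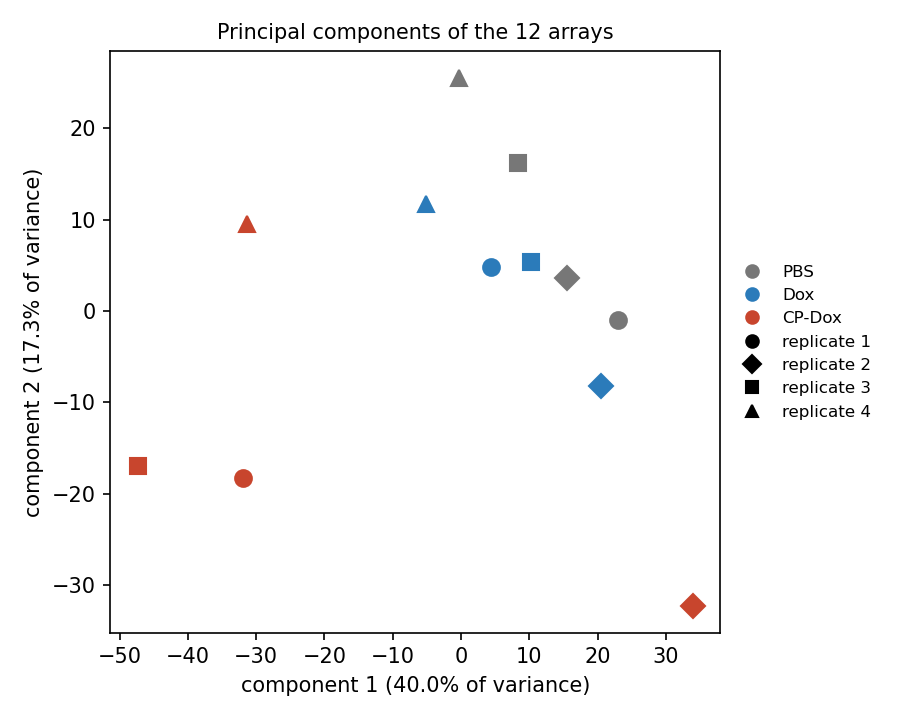
Principal components 1 and 2 of the 12 arrays, with the share of variance in percent on each axis; colours give the treatment and symbols the replicate number. CP-Dox replicates 1, 3 and 4 lie at the left, and CP-Dox replicate 2 lies at the lower right.

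The comparison of CP-Dox with PBS asked how tumours given the polypeptide-bound drug differed from those given PBS. No group received the carrier alone, so that effects of the drug and of the carrier cannot be told apart. The largest rises and falls were taken only from genes past the threshold whose groups did not overlap. The 8 largest such rises included a p53 target, a pair of neutrophil genes and a mast cell tryptase gene. Ephx1, which encodes microsomal epoxide hydrolase, rose by 3.07 ± 0.38 (8.41-fold), Trp53inp1, a p53 target that promotes cell death and autophagy, rose by 2.51 ± 0.35 (5.68-fold), and Anxa8, which encodes an annexin, rose by 3.27 ± 0.45 (9.65-fold). The transferrin receptor gene Tfrc fell by 2.10 ± 0.39 on the log2 scale, and Ung, which encodes uracil-DNA glycosylase, fell by 1.80 ± 0.18. In all, 691 of 12393 genes changed, 291 up and 400 down (limma, adjusted p under 0.05), and 90 of them changed at least 2-fold, 62 up and 28 down.

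The other large rises were those of Lcn2 (2.40 ± 0.63), S100a8 (2.09 ± 0.50) and Car4 (2.19 ± 0.40), and of Tph1 (2.29 ± 0.35) and Tpsb2 (2.04 ± 0.33), which encode tryptophan hydroxylase 1 and a mast cell tryptase. All 8 genes were higher in each CP-Dox tumour than in every PBS tumour, as the rule for naming them requires (limma adjusted p from 0.00290 to 0.0483). Among the falls, Cbr2, a carbonyl reductase gene, fell by 2.03 ± 0.35, Mtm1, a phosphoinositide phosphatase gene, by 1.95 ± 0.20, Ccne2, which encodes cyclin E2, by 1.69 ± 0.33, and Npl by 1.46 ± 0.32. Alas2, the erythroid form of the first enzyme of haem synthesis, fell by 1.48 ± 0.24, and Dctpp1, which removes modified nucleotides from the nucleotide pool, fell by 1.41 ± 0.21 (limma adjusted p for all 8 falls from 0.00237 to 0.0248). For Mtm1, 2 of its 3 probe sets had the same direction. The other probe set of Tpsb2 was at 0.29 and did not pass, and that of Trp53inp1 was at 1.09. Of the 691 genes, 637 had no overlap between the 4 CP-Dox and the 4 PBS values. Over all genes, 12.1% were without overlap, where chance gives 2.86%.

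**Figure D2:**
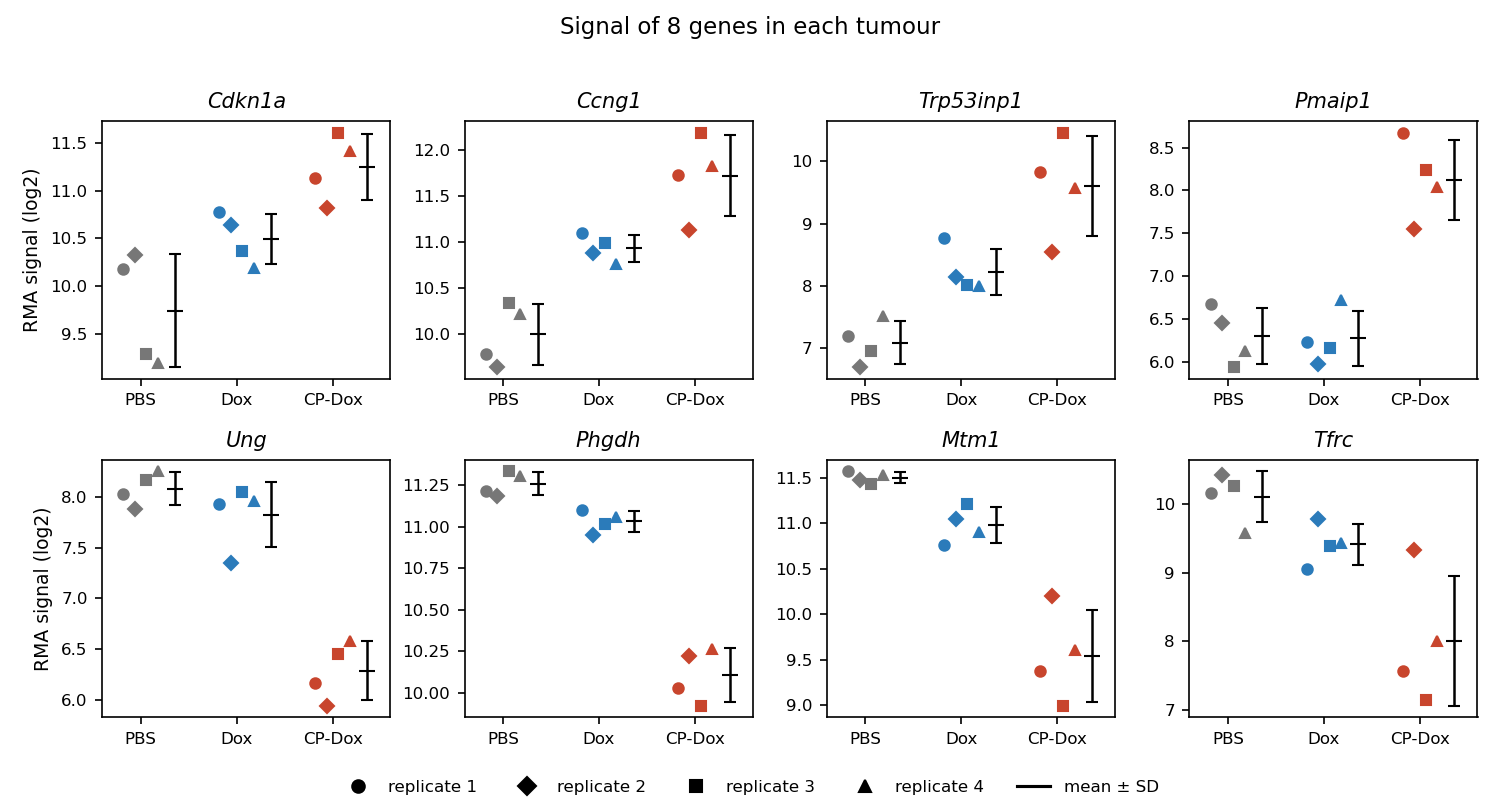
RMA signal (log2) of 8 genes in each of the 12 tumours by group, with bars for mean ± SD (n = 4). Ung lies at 5.94 to 6.58 in the CP-Dox tumours and at 7.35 to 8.05 in the Dox tumours, and Pmaip1 at 7.55 to 8.68 and 5.97 to 6.72.

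Of 28 measured p53 targets, 11 rose and none fell, with a median log2 fold change of 0.65 (camera adjusted p = 3.47e-12, and adjusted p = 0.134 with an estimated correlation). Adjusted over the list alone, 15 rose. Cdkn1a, which encodes the cell cycle inhibitor p21, rose 2.83-fold (95% confidence interval of the log2 fold change 0.91 to 2.09), Mdm2, the main negative regulator of p53, by 1.35 ± 0.26, and Ccng1, which encodes cyclin G1, by 1.72 ± 0.21. Pmaip1, which encodes the pro-apoptotic protein Noxa, rose by 1.83 ± 0.24, and Zmat3, an RNA-binding p53 target, rose by 1.31 ± 0.20. The list mean was highest in CP-Dox replicates 3 and 1 (1.21 and 0.89 above the PBS mean), the arrays with keratinocyte markers, and lay at 0.72 in replicate 4 and 0.41 in replicate 2. Without CP-Dox replicate 2, 17 members rose. Among apoptosis genes, 0 of 24 passed the threshold (median 0.28, camera adjusted p = 0.00616, and adjusted p = 0.512 with an estimated correlation), and the lowest p was that of Bcl2l11, which encodes the pro-apoptotic protein Bim, at 0.66 ± 0.18 (limma adjusted p = 0.0565). Without CP-Dox replicate 2, 8 of them rose.

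Of 21 ribosome biogenesis genes, 7 fell and none rose (median -0.45, camera adjusted p = 2.01e-08, and adjusted p = 0.374 with an estimated correlation), and 14 fell when adjusted over the list alone. Without CP-Dox replicate 2, 15 of the 21 fell over all genes. The list mean was -0.67 to -0.22 in the CP-Dox tumours, highest in replicate 2, and overlapped with PBS replicate 4 at -0.36, while the other PBS tumours were at 0.05 to 0.16. Nop56, a component of box C/D nucleolar ribonucleoproteins, fell by 0.89 ± 0.15, Wdr12 by 0.68 ± 0.10, and Gar1 by 0.66 ± 0.12. Of 26 DNA replication and S phase genes, 4 fell (12 adjusted over the list alone; median -0.73, camera adjusted p = 1.80e-08, and adjusted p = 0.512 with an estimated correlation). These were Ccne1 (fell by 0.78 ± 0.14), Ccne2, the thymidine kinase gene Tk1 (fell by 1.39 ± 0.30) and Pcna (fell by 0.65 ± 0.15). Of 23 DNA repair and checkpoint genes, 4 fell (8 adjusted over the list alone; median -0.35, camera adjusted p = 0.00118, and adjusted p = 0.512 with an estimated correlation). They were H2ax, the histone variant phosphorylated at DNA breaks (fell by 1.12 ± 0.13), the Ku70 gene Xrcc6 (fell by 0.73 ± 0.08), Xrcc1 (fell by 0.44 ± 0.10) and Parp1 (fell by 0.49 ± 0.13).

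Of 27 G2/M and mitosis genes, 1 fell, also when adjusted over the list alone, and it was the cyclin A2 gene Ccna2 (fell by 1.08 ± 0.21; list median -0.58, camera adjusted p = 1.84e-05, and adjusted p = 0.512 with an estimated correlation). The size of this group's difference rested on 1 tumour: the list mean was -1.67 in CP-Dox replicate 2 and -0.16, -0.29 and -0.15 in replicates 1, 3 and 4, with PBS replicate 4 at -0.17. Repair genes overlapped as well, at -0.13 in CP-Dox replicates 1 and 3 and -0.19 in PBS replicate 4. S phase genes were also lowest in that tumour, at -1.61 against -0.48 to -0.38 in the other CP-Dox tumours. Without CP-Dox replicate 2 the medians were -0.26 for G2/M, -0.44 for S phase and -0.17 for repair genes, and the repair list was no longer called (camera adjusted p = 0.0671). More members passed without it, however: 6 G2/M, 8 S phase and 6 repair genes fell, and 1 repair gene rose. Mki67 and Top2a, markers of proliferation, differed by -0.72 ± 0.34 and -0.36 ± 0.44 and did not pass the threshold (limma adjusted p = 0.231 and 0.638). Top2a was at 8.96 in CP-Dox replicate 2 and at 11.08 to 11.26 in the other CP-Dox tumours, so that its negative sign rested on replicate 2. Of 7 histone genes, 2 fell and 1 rose, also over the list alone (camera adjusted p = 0.240, and adjusted p = 0.512 with an estimated correlation).

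Of 23 lysosome and autophagy genes, 6 rose (12 adjusted over the list alone), none fell and 17 did not pass, with a median of 0.37 (camera adjusted p = 8.66e-09, and adjusted p = 0.107 with an estimated correlation). Without CP-Dox replicate 2, 11 of them rose over all genes. The proton pump subunit genes Atp6v0d1 and Atp6v1h rose by 0.37 ± 0.07 and 0.48 ± 0.11, Map1lc3b, which encodes the autophagosome protein LC3B, by 0.41 ± 0.09, and the cathepsin B gene Ctsb by 0.38 ± 0.08. Stress genes moved apart. Among 24 genes of the unfolded protein and integrated stress responses, 3 rose and 4 fell (3 and 5 over the list alone; camera adjusted p = 0.853, and adjusted p = 0.880 with an estimated correlation): the lipoprotein receptor gene Vldlr rose by 1.95 ± 0.26, while Phgdh and Shmt2, enzymes of serine and one-carbon metabolism, fell by 1.15 ± 0.09 and 1.19 ± 0.17, and the kinase-like gene Trib3 fell by 0.85 ± 0.14. Of 13 heat shock genes, Hspa1a rose by 0.90 ± 0.15 and the mitochondrial chaperone genes Hspe1 and Hspd1 fell by 0.58 ± 0.11 and 0.67 ± 0.17 (1 rose and 3 fell over the list alone; camera adjusted p = 0.993, and adjusted p = 0.997 with an estimated correlation). Of 21 hypoxia and glycolysis genes, 1 rose, Ddit4 at 1.03 ± 0.26 (1 rose and 1 fell over the list alone; camera adjusted p = 0.993, and adjusted p = 0.997 with an estimated correlation), and of 20 NRF2 and antioxidant genes none passed (camera adjusted p = 0.267, and adjusted p = 0.512 with an estimated correlation).

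Doxorubicin transport and metabolism genes gave 0 calls of 14 (median 0.20, camera adjusted p = 0.0168, and adjusted p = 0.316 with an estimated correlation), with the drug efflux pump genes Abcb1a and Abcb1b at 0.45 ± 0.19 and 0.23 ± 0.15. Without CP-Dox replicate 2, 4 of the 14 rose. Cholesterol and lipid synthesis genes gave 0 calls of 18 (6 fell over the list alone; median -0.50, camera adjusted p = 4.83e-04, and adjusted p = 0.512 with an estimated correlation). Their list mean was -0.86, -0.95 and -0.92 in CP-Dox replicates 1, 3 and 4 and 0.16 in replicate 2, and without replicate 2 a further fit called 10 members, all lower. The farnesyl diphosphate synthase gene Fdps, for instance, was at -1.40 ± 0.37 with all arrays (limma adjusted p = 0.0513) and fell by 1.88 without it. Txnip, a thioredoxin-binding protein gene, differed by 1.25 ± 0.48 (limma adjusted p = 0.147) and rose by 1.85 without it. Because replicate 2 lay apart on the cholesterol list, leaving it out favours such calls by construction, and they are not separate support. Of 20 extracellular matrix remodelling genes, 0 passed (camera adjusted p = 0.0214, and adjusted p = 0.512 with an estimated correlation).

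The means of mast cell, endothelial, neutrophil and fibroblast markers were higher in each CP-Dox tumour than in every PBS tumour. Of 11 mast cell and basophil markers, 9 rose, also over the list alone, and the median log2 fold change was 1.61 (camera adjusted p = 3.17e-11, and adjusted p = 0.206 with an estimated correlation). Hdc, which encodes histidine decarboxylase, rose by 1.73 ± 0.22 (3.32-fold), the stem cell factor receptor gene Kit by 1.36 ± 0.19, and Ms4a2, a subunit of the high-affinity IgE receptor, by 1.14 ± 0.20. The list mean exceeded the PBS mean by 1.02 to 1.88 in the 4 CP-Dox tumours. Of 16 endothelial markers, 3 rose (5 adjusted over the list alone; median 0.38, camera adjusted p = 6.19e-07, and adjusted p = 0.206 with an estimated correlation): Plvap by 1.23 ± 0.16, Pecam1 by 1.02 ± 0.15 and the endomucin gene Emcn by 0.86 ± 0.13. Of 11 neutrophil markers, S100a8 and Lcn2 rose (4 over the list alone; median 0.01, camera adjusted p = 0.0434, and adjusted p = 0.512 with an estimated correlation). Of 17 fibroblast markers, the decorin gene Dcn rose by 0.52 ± 0.11 and Thy1 by 0.74 ± 0.19 (2 over the list alone; camera adjusted p = 0.00195, and adjusted p = 0.316 with an estimated correlation). Thy1 was also the 1 of 20 T cell and natural killer cell markers that rose (camera adjusted p = 0.0490, and adjusted p = 0.711 with an estimated correlation), and 8 of the 20 rose without CP-Dox replicate 2.

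Interferon and immune genes differed between the CP-Dox tumours. The mean of 28 interferon response genes exceeded the PBS mean by 1.53 to 1.61 in CP-Dox replicates 1, 3 and 4 and lay at -1.88 in replicate 2, and 0 of the 28 genes passed the threshold (camera adjusted p = 0.00118, and adjusted p = 0.633 with an estimated correlation). Without CP-Dox replicate 2, where list members were counted only after the data were seen, 27 of the 28 rose with a median of 1.52, among them Ifit3 (2.61, limma adjusted p = 0.00225) and the antiviral GTPase gene Mx1 (2.50). Gzmb, Prf1 and Ifng, effector genes of cytotoxic lymphocytes, were at 1.28 ± 0.97, 0.97 ± 0.76 and 1.65 ± 0.95 with all arrays and rose by 2.48, 1.89 and 2.68 without replicate 2. Antigen presentation genes went the same way, with 0 calls of 13 (camera adjusted p = 0.0434, and adjusted p = 0.633 with an estimated correlation) and 4 rises without replicate 2. Inflammatory cytokine and NF-kB genes gave 1 rise of 27, that of Nfkbia (0.58 ± 0.13; camera adjusted p = 0.0930, and adjusted p = 0.633 with an estimated correlation), and 10 without replicate 2.

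Of 19 macrophage markers none passed (camera adjusted p = 0.605, and adjusted p = 0.880 with an estimated correlation), and the lowest p was that of the scavenger receptor gene Cd163 (-1.73 ± 0.52, limma adjusted p = 0.0799). Without CP-Dox replicate 2, 6 of them rose and 2 fell, and the list was called up (median 0.36, camera adjusted p = 0.0382, and adjusted p = 0.439 with an estimated correlation). All 14 keratinocyte and skin markers were higher on average (camera adjusted p = 1.84e-05, and adjusted p = 0.512 with an estimated correlation), with 0 calls, and they were high in none of the arrays but CP-Dox replicates 1 and 3: Krt14 was at 10.17 and 11.86 there and at 5.48 to 5.57 in the other CP-Dox tumours. Skeletal muscle markers gave 0 calls of 16 (camera adjusted p = 0.149, and adjusted p = 0.818 with an estimated correlation). Of 10 adipocyte markers, Lipe (0.81 ± 0.17) and Lpl (1.67 ± 0.42) rose (camera adjusted p = 0.0930, and adjusted p = 0.512 with an estimated correlation), and of 15 epithelial markers Cdh1, the E-cadherin gene, rose (1.25 ± 0.33; camera adjusted p = 0.244, and adjusted p = 0.512 with an estimated correlation). Cdh1 was highest in the arrays with keratinocyte markers, at 7.03 and 7.88 in CP-Dox replicates 1 and 3, compared with 5.98 and 6.29 in replicates 2 and 4 and at most 5.77 in PBS. Of 6 erythroid and platelet markers, Alas2 fell (2 fell over the list alone; camera adjusted p = 0.179, and adjusted p = 0.512 with an estimated correlation). No B cell or plasma cell marker of 10 (camera adjusted p = 0.948, and adjusted p = 0.959 with an estimated correlation) and no dendritic cell marker of 10 (camera adjusted p = 0.971, and adjusted p = 0.997 with an estimated correlation) passed. In these last lists and in the hypoxia list, the median was below 0 while the test pointed up.

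**Figure D3:**
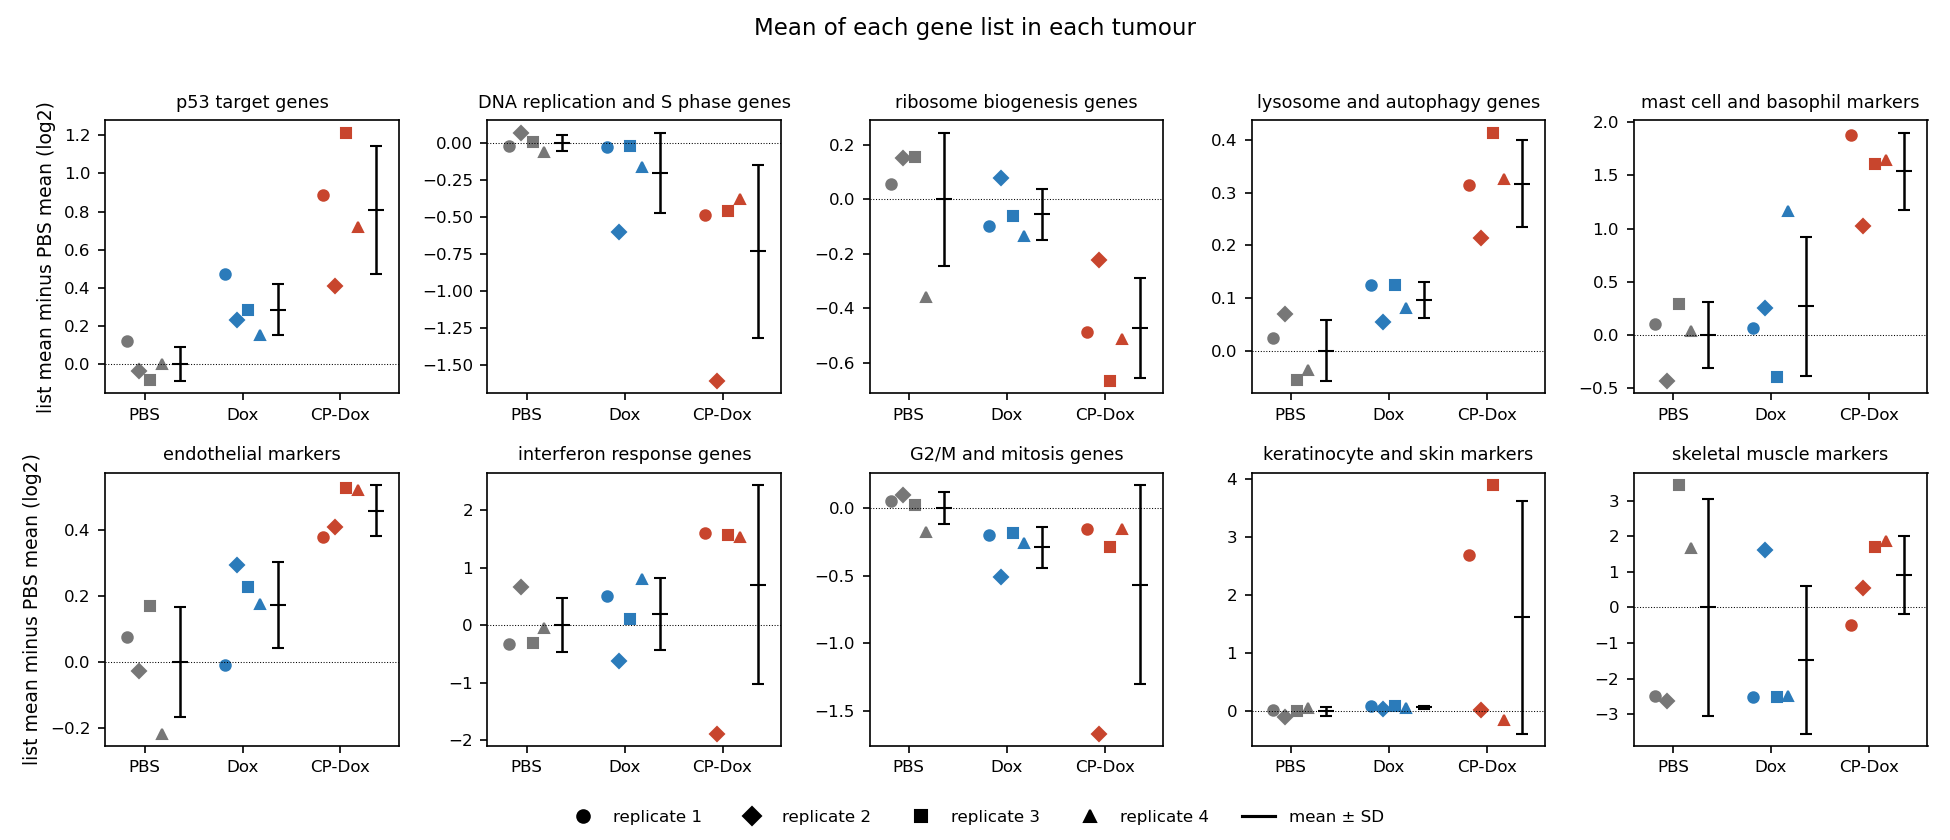
Mean log2 signal of 10 gene lists in each tumour, minus the PBS group mean, by treatment group, with bars for mean ± SD (n = 4). Mast cell markers lie at 1.02 to 1.88 in the CP-Dox tumours, and interferon genes lie at -1.88 in CP-Dox replicate 2 and 1.53 or more in the other CP-Dox tumours.

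By camera with a preset inter-gene correlation, 18 of the 31 lists differed between CP-Dox and PBS, 13 up and 5 down, and none did with an estimated correlation (lowest adjusted p = 0.107 with an estimated correlation). Of the 18 calls, 12 were kept without any single array. The others had their highest camera adjusted p without CP-Dox replicate 4 for T cell (0.603), antigen presentation (0.352) and neutrophil genes (0.302), without CP-Dox replicate 2 for extracellular matrix (0.410) and repair genes (0.0671), and without PBS replicate 4 for doxorubicin transport genes (0.0579). The number of changed genes moved with single tumours: it was 246, 2363, 214 and 412 without CP-Dox replicate 1, 2, 3 or 4, and 396 and 272 without PBS replicate 1 or 3, and all 691 genes were among the 2363. The excess of falls was not kept without CP-Dox replicate 2 (1227 up and 1136 down), and it was small with array weights (1306 up and 1359 down). Of the 60 calls of named genes, 25 were lost without some single array, and with the means of the muscle and keratinocyte markers as covariates, which were added after the data were seen, 48 genes passed, 42 of them among the 691, and 48 of the 60 named calls were lost. The keratinocyte mean varied almost only within CP-Dox (SD 2.00, against 0.02 in Dox and 0.07 in PBS). The smaller count therefore cannot separate an effect of neighbouring tissue from a loss of precision.

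Free Dox was compared with PBS to show the response to the unconjugated drug. No gene passed the threshold by limma, and 558 of 12393 had an unadjusted p under 0.05, where chance gives 619.65. The genes with the lowest p failed it: the beta-globin gene Hbb-b2 was at -1.40 ± 0.18 (limma adjusted p = 0.0783), Alas2 at -1.70 ± 0.24 (limma adjusted p = 0.0825), Zmat3 at 1.05 ± 0.20, Npepl1 at -0.36 ± 0.07 and Ier5l at -0.61 ± 0.12. In each of these 5 genes the 4 Dox values lay beyond all 4 PBS values. Overlap-free genes made up 3.84% of all, where chance gives 2.86%. The limma fit pooled the spread over all groups, and some CP-Dox replicates differed from each other more than any Dox or PBS replicates. The counts by limma in this comparison may therefore be too low.

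Of the 28 p53 targets, 21 had a positive log2 fold change under Dox and 5 rose when adjusted over the list alone (median 0.26, camera adjusted p = 1.52e-07, and adjusted p = 0.489 with an estimated correlation). Ccng1 was at 0.94 ± 0.21 (95% confidence interval 0.47 to 1.40), Trp53inp1 at 1.14 ± 0.35, Cdkn1a at 0.75 ± 0.27 (0.16 to 1.34) and Mdm2 at 0.54 ± 0.26 (-0.03 to 1.11). All 27 G2/M genes were below 0 (median -0.28, camera adjusted p = 7.26e-05, and adjusted p = 0.711 with an estimated correlation). Camera with the preset correlation called 13 lists, 7 up and 6 down, and none with an estimated correlation (lowest adjusted p = 0.489 with an estimated correlation). Without PBS replicate 2, the preset correlation called 8 lists. The p53 and G2/M calls were kept without any single array, and each of the other 11 was lost without at least 1. Besides p53 targets, the lists called up were lysosome (adjusted p = 0.00844), endothelial (0.00136), mast cell (0.0129), macrophage (0.0269), fibroblast (0.0415) and antigen presentation genes (0.0440). Besides G2/M genes, those called down were cholesterol (0.00123), skeletal muscle (0.00136), S phase (0.00665), erythroid and platelet (0.0146) and repair genes (0.0440). The mast cell and antigen presentation means were highest in Dox replicate 4 (1.16 and 0.71, against -0.40 to 0.26 and 0.02 to 0.18 in the other Dox tumours), and without it neither list was called (camera adjusted p = 0.897 and 0.561, and 0.611 for antigen presentation genes without PBS replicate 1). The highest camera adjusted p without 1 array was 0.522 for repair and 0.0745 for cholesterol genes (without PBS replicate 2), 0.507 for muscle and 0.0794 for lysosome genes (without PBS replicate 3), 0.258 for macrophage and 0.0741 for erythroid genes (without PBS replicate 1), 0.0646 for endothelial genes (without PBS replicate 4), and 0.321 for S phase and 0.291 for fibroblast genes (without Dox replicate 2). Adjusted over the list alone, 1 endothelial gene rose and 1 erythroid gene fell, and no other member of these lists passed. In the other 18 lists no member passed. Muscle markers were low in 3 of the 4 Dox tumours and in 2 of the 4 PBS tumours. Mki67, Top2a and Txnip differed by -0.28 ± 0.34, -0.19 ± 0.44 and 0.41 ± 0.48, and Abcb1a and Abcb1b by 0.23 ± 0.19 and 0.20 ± 0.15. Leaving out CP-Dox replicate 1 or 4, which changes only the pooled spread, gave 1 and 2 genes, and every other array left out gave 0.

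CP-Dox and free Dox were compared directly to see whether tumours under the drug forms differ. Without a group given the carrier alone and without the doses, drug form, amount of drug and carrier cannot be told apart. The 18S ribosomal RNA control signal also separated the groups, at 7.49 to 12.04 in CP-Dox and 6.11 to 7.14 in Dox arrays. Its bearing on the comparison was not tested. Phgdh, the first enzyme of serine synthesis, fell by 0.92 ± 0.09 relative to Dox, Shmt2 by 1.02 ± 0.17, Ung by 1.54 ± 0.18 and H2ax by 0.86 ± 0.13. Pmaip1 rose by 1.86 ± 0.24 (3.62-fold) and Anxa8 by 2.58 ± 0.45 (5.97-fold). In all, 28 genes changed, 7 up and 21 down (limma, adjusted p under 0.05), 8 of them at least 2-fold, and 27 of the 28 were also called in CP-Dox against PBS. The excess of falls was absent without CP-Dox replicate 2 (591 up and 559 down) and without Dox replicate 4 (11 up and 7 down).

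The other rises were those of A4galt, a glycolipid synthase gene (1.79 ± 0.30), the nuclear non-coding RNA Malat1 (1.78 ± 0.27), Ak1 (0.94 ± 0.16), Chst15 (0.55 ± 0.09) and Ubap1 (0.46 ± 0.07). Further falls were those of Cbr2, which fell by 2.07 ± 0.35, Mtm1, which fell by 1.44 ± 0.20, Cdca7, which fell by 0.90 ± 0.14, and Timm8a1, which fell by 0.84 ± 0.14. The limma adjusted p of the 15 genes named here ranged from 0.00433 to 0.0499. In all 28 genes, the CP-Dox and Dox tumours did not overlap. Over all genes 9.63% were without overlap, where chance gives 2.86%. For Malat1, 4 of 5 probe sets, for Mtm1, 2 of 3 and for Ak1, 1 of 2 had the direction given, and with every probe set tested on its own none of Anxa8, Shmt2, Timm8a1 and Ak1 passed. Genes whose difference between the drug forms did not pass included Cdkn1a at 0.75 ± 0.27 (95% confidence interval 0.16 to 1.34), Mdm2 at 0.81 ± 0.26 (0.24 to 1.38), Trp53inp1 at 1.37 ± 0.35 and Ccng1 at 0.79 ± 0.21. Top2a, Mki67, Txnip, Abcb1a and Abcb1b were at -0.16 ± 0.44, -0.44 ± 0.34, 0.84 ± 0.48, 0.22 ± 0.19 and 0.03 ± 0.15.

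By camera with the preset correlation, 14 lists differed between the drug forms, 10 up and 4 down, and none did with an estimated correlation (lowest adjusted p = 0.181 with an estimated correlation). Mast cell markers had the lowest p (median 1.18, camera adjusted p = 1.20e-11, and adjusted p = 0.270 with an estimated correlation). No mast cell gene passed over all genes, whereas 9 of 11 rose when adjusted over the list alone, for example Tpsb2 (1.75 ± 0.33, limma adjusted p = 0.0578 over all genes). Without CP-Dox replicate 2, 10 of the 11 rose over all genes. The drug forms overlapped on this list, since its mean was 1.16 in Dox replicate 4 and 1.02 in CP-Dox replicate 2. Ribosome biogenesis genes were called down (median -0.40, camera adjusted p = 2.26e-09, and adjusted p = 0.337 with an estimated correlation), with 0 calls over all genes and 13 falls of 21 over the list alone. Of the p53 targets 1 rose (8 over the list alone; median 0.36, camera adjusted p = 5.36e-08, and adjusted p = 0.270 with an estimated correlation), and of the repair genes 2 fell (2 over the list alone; camera adjusted p = 0.00671, and adjusted p = 0.593 with an estimated correlation). The other lists called up were lysosome (adjusted p = 1.63e-07), keratinocyte (8.08e-06), endothelial (5.15e-05), skeletal muscle (5.15e-05), apoptosis (0.00449), interferon (0.00449), NRF2 and antioxidant (0.00937) and fibroblast genes (0.0381), and the others called down were S phase (9.09e-07) and G2/M genes (0.0229). Over the list alone, 3 lysosome and 4 endothelial genes and 1 fibroblast gene rose and 2 S phase genes fell. In the stress lists, which were not called, Phgdh and Shmt2 were the 2 members that fell (2 rose and 5 fell over the list alone), and of the heat shock genes none passed over all genes (2 rose and 4 fell over the list alone). In the epithelial, hypoxia and dendritic cell lists, not called either, the median was below 0 while the test pointed up. Keratinocyte markers were high in CP-Dox replicates 1 and 3 alone, and interferon genes were low in CP-Dox replicate 2. Without that tumour 19 interferon genes and 9 p53 targets rose over all genes, and 6 ribosome biogenesis genes fell. The G2/M list then had a median of -0.01, pointed up and was not called (camera adjusted p = 0.144). Of the 14 calls, 8 were kept without any single array. Besides G2/M, those lost had their highest camera adjusted p without CP-Dox replicate 2 for repair (0.403) and NRF2 genes (0.0570), without CP-Dox replicate 1 for interferon genes (0.155), without Dox replicate 2 for apoptosis genes (0.0511), and without Dox replicate 4 for fibroblast genes (0.262).

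The number of genes that differed between the drug forms rested on single arrays. It was 1150 without CP-Dox replicate 2, with all 28 genes among them, and 1, 2 and 8 without CP-Dox replicate 1, 3 or 4. Without Dox replicate 1, 2, 3 or 4 it was 1, 6, 1 and 18, and without PBS replicate 1 or 2 it was 4 and 3. With the replicate number as a block 8 genes passed, 5 of them among the 28. A fit of the 2 groups alone called 0 genes, with the muscle and keratinocyte means as covariates, added later, 3 genes passed, and each of the 16 named calls was lost in at least 1 alternative.

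The responses to the drug forms were set side by side to see how far they overlapped. Of the 691 genes called under CP-Dox, 656 (94.9%) had the same direction under Dox, and the median ratio of the Dox to the CP-Dox log2 fold change was 0.328. At an unadjusted p under 0.05 under Dox, 90 of the 691 genes were higher and 98 lower under both drug forms and 0 were opposite. Since the PBS tumours are shared and favour equal directions, and no expected number that allows for this was computed, these counts do not measure an excess. Since Dox against PBS called 0 genes, no gene could be called in both comparisons. Across genes, which are not independent replicates, the log2 fold changes had a correlation of 0.501. The shared PBS tumours alone give a correlation: unchanged groups simulated against them had a mean of 0.451 over 100 draws, with 95% of draws from -0.27 to 0.93, and the covariance was 0.0363 against a simulated 0.0284. With the PBS tumours split so that each comparison used 2 of them, the correlation was -0.19 to 0.33 over the 6 splits, the share of the 691 genes with the same direction was 60.1% to 88.9%, and the median ratio was 0.0667 to 0.271. The covariance with split PBS tumours ranged from -0.0274 to 0.0277. The 691 genes were called against all PBS tumours, so that their shares and ratios after the split may still be raised.

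**Figure D4:**
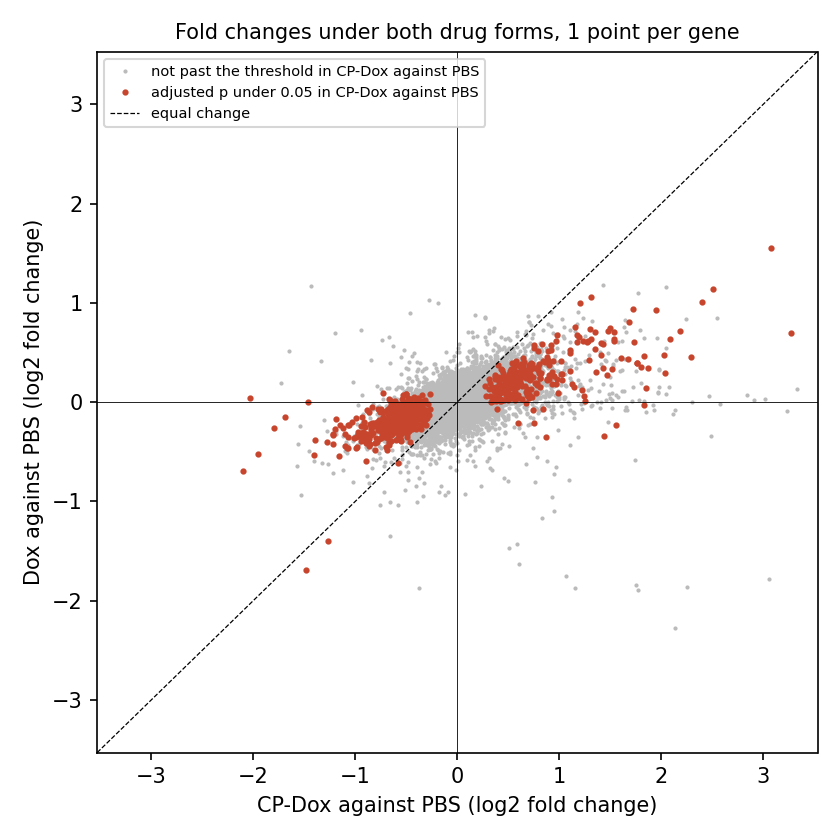
Log2 fold change against PBS under CP-Dox (horizontal axis) and Dox (vertical axis), with 1 point per gene for 12393 genes; coloured points are the 691 genes called in CP-Dox against PBS. Of these, 656 lie on the same side of 0 on both axes, in a set of genes chosen for their change under CP-Dox.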

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

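The tests of explanations and the counts over other splits of the arrays given in this part were chosen after the results were seen. Each of 36 measures was searched in each group of 4 arrays for a tumour far from the other 3. Of 108 groups, 9 had such a tumour, where chance gives about 5.4. Besides these, signals in probe sets left out of the comparisons are given.

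CP-Dox replicate 2 stood far from the other CP-Dox tumours in 6 lists (values are list means relative to PBS, log2). G2/M genes were at -1.67 against -0.29 to -0.15 in the others, S phase genes at -1.61 against -0.48 to -0.38, repair genes at -0.80 against -0.23 to -0.13, apoptosis genes at -0.21 against 0.41 to 0.51, interferon genes at -1.88 against 1.53 to 1.61, and cholesterol synthesis genes at 0.16 against -0.95 to -0.86. Against a PBS tumour under the wrong label, its p53 target mean was 0.41, above the PBS range of -0.09 to 0.12, and against degraded RNA, its beta-actin 3' minus 5' signal was 0.54, within the 0.38 to 0.64 of the other 11 arrays. A Dox tumour under the wrong label stays open: at 24.3% of 1036 genes called for the other CP-Dox tumours it lay beyond all PBS and Dox arrays on the CP-Dox side, within the 3.20% to 50.0% of PBS and Dox arrays left out in turn, at 30.2% it lay beyond them on the other side, and at 10.04% it reached the level of the other CP-Dox tumours, within the 0.246% to 12.5% of the arrays left out. No biological explanation was tested, since the labels name no difference between mice of a group.

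Mast cell and basophil markers were higher in every CP-Dox tumour than in every PBS tumour. A lower share of tumour cells would raise macrophage markers alike only if the drug left macrophages unchanged, which was not tested. The mast cell mean minus the macrophage mean differed by 1.54 between CP-Dox and PBS (lowest CP-Dox tumour 1.27, highest PBS tumour 0.31). Relative to PBS, the CP-Dox means were 0.73 for neutrophil, 0.46 for endothelial and 0.34 for fibroblast markers. They were -0.002 for macrophage, -0.01 for B cell and -0.03 for dendritic cell markers. The mast cell mean, at 1.54, lay above each of these, but a lower share of tumour cells stays open as a part of the cause. The neutrophil mean rested on part of its list, since the median log2 fold change was 0.01, with 7 of 11 members above 0. The macrophage means ranged from -0.59 to 0.37 over the CP-Dox tumours. Without CP-Dox replicate 2 the macrophage list was called up (median 0.36, camera adjusted p = 0.0382, and adjusted p = 0.439 with an estimated correlation). Against epidermis in the samples, the lower mast cell mean of the 2 CP-Dox tumours without keratinocyte markers was 1.02, above the highest PBS tumour at 0.29. Deeper skin or connective tissue in the samples, more mast cells in the tumours and a change of expression within mast cells stay open and were not tested, so that a treatment effect is a hypothesis only.

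Probe sets of haemoglobin genes that carry several symbols were lower in the drug-treated tumours, with a mean (4 probe sets) of 12.62 ± 0.40 in PBS, 8.84 ± 0.44 in Dox and 9.89 ± 1.76 in CP-Dox tumours (SD, n = 4). The Dox minus PBS difference was -3.78, which 4 of 4 Dox tumours showed (two-sided exact permutation p = 0.0286, the smallest that 70 splits allow, adjusted p = 0.0857 over 3 comparisons, limma adjusted p over all probe sets = 0.380 for each of the 4 probe sets), and CP-Dox against PBS was at -2.73 (exact permutation p = 0.0571, adjusted p = 0.0857), where all 4 probe sets passed by limma over all probe sets (adjusted p from 0.0368 to 0.0391). The unadjusted limma p was lower for Dox (1.07e-04 to 1.23e-04) than for CP-Dox (0.00143 to 0.00166). The adjusted p depends on how many other probe sets have a low p in the same comparison. It therefore does not show a better supported fall in CP-Dox than in Dox. Less blood in the tumour pieces stays open, since only 2 platelet genes had a signal above the median of all genes and their median difference was -0.26 (Itga2b 0.18, Pf4 -0.71), too few to decide. CP-Dox replicate 4 had the highest CP-Dox value, 12.35, within the PBS range, and a p53 target mean of 0.72 against at most 0.12 in PBS, which argues against a lack of drug effect there. An effect of the drug on red cells or vessels was not tested.

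Single Dox tumours also stood apart. Heat shock genes were at 0.36 in Dox replicate 2 against -0.12 to -0.05 in the others, and skeletal muscle markers at 1.63 against -2.53 to -2.49. Dox replicate 2 also had the lowest Dox means of G2/M (-0.51), S phase (-0.60), repair (-0.25), apoptosis (-0.22) and interferon genes (-0.63), none of them flagged. CP-Dox replicate 2 was low in the same lists. The deviations of these 2 arrays from their group means had a correlation of 0.51, the highest of 12 same-numbered pairs. The reason was not tested. Neutrophil markers were at 0.96 in Dox replicate 4 against -0.04 to 0.12. Among probe sets without a single gene symbol, 109 differed between CP-Dox and PBS with limma over all probe sets, 51 with several symbols and 58 with none.

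Other splits of the 8 arrays of a comparison were fitted the same way. For CP-Dox against PBS, 2 of the 35 splits, the real one included, gave at least the 691 genes found, and the highest other gave 1000, so that chance cannot be excluded. That split places PBS replicate 4 with CP-Dox replicates 1, 3 and 4, and CP-Dox replicate 2 with PBS, which points to the structure of the samples described above. For CP-Dox against Dox, 2 of 35 splits gave at least 28 genes and the highest other, with Dox replicate 4 in the place of CP-Dox replicate 2, gave 676, many times the real count, so that chance cannot be excluded and the structure of the samples shows again. For Dox against PBS, where limma called 0 genes (558 at an unadjusted p under 0.05), 35 of 35 splits gave at least that number, as any split must, and the highest other gave 0, so that this count says nothing about chance.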

How the results depend on the processing

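The covariates for muscle and skin markers were chosen after the data were seen, and the other alternatives were planned. In the CP-Dox comparison with PBS, the 691 genes became 1209 probe sets when each probe set was tested on its own (more tests). They became 2665 genes with array weights (1306 higher and 1359 lower), 198 in a fit of those groups alone, and 48 with the covariates. The fit of those groups alone has fewer arrays and another estimate of the spread, which the main fit pools over the 3 groups. Pairs of replicates differed with an SD of 0.32 to 0.78 in CP-Dox, 0.22 to 0.46 in Dox and 0.29 to 0.50 in PBS. The pooled standard errors may thus be too small for the CP-Dox comparisons and too large for Dox against PBS. By construction, 90 passed at 2-fold or more and 143 at an adjusted p under 0.01. Leaving out 1 array gave 214 (without CP-Dox replicate 3) to 2363 (without CP-Dox replicate 2, 1227 higher and 1136 lower). With arrays centred on their medians 719 passed, 216 higher and 503 lower, against 291 and 400. The other alternatives gave 588 to 995, the highest with the replicate block. Except where the construction shows it, the cause was not tested.

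In the Dox comparison with PBS, where limma called 0 genes (558 at an unadjusted p under 0.05), another round of quantile normalization and the fit of those groups alone gave 2 each (Hbb-b2 and Alas2), and leaving out 1 array gave 0 to 2 (1 without CP-Dox replicate 1, 2 without CP-Dox replicate 4). The cause was not tested. In the direct comparison of the drug forms, 28 genes became 46 with another quantile normalization, 47 without the dimmest 40% of genes (fewer tests), 1960 with array weights (864 higher and 1096 lower), 0 in the fit of those groups alone, 8 with the replicate block (5 of them among the 28), 3 with the covariates, 8 at 2-fold or more, and 1 at an adjusted p under 0.01. Leaving out 1 array gave 1 (without CP-Dox replicate 1, Dox replicate 1 or Dox replicate 3) to 1150 (without CP-Dox replicate 2, 591 higher and 559 lower). With arrays centred on their medians 37 passed, 4 higher and 33 lower, against 7 and 21. The other alternatives gave 34 to 40. The cause was not tested.

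Of the named genes, 60 of 139 were called in CP-Dox against PBS, 12 of them in all alternatives, with 48 lost in some and 0 reversed. In CP-Dox against Dox, 16 of 141 were called and 16 were lost in some alternative, with 0 reversed. Centring moved the median log2 fold change of all genes to at most -0.09.

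Lists called by camera went from 18, 13 and 14 in the 3 comparisons to 0, 0 and 0 with an estimated correlation. The other alternatives gave 13 to 19, 10 to 16 and 13 to 15, and leaving out 1 array gave 15 to 19, 8 (without PBS replicate 2) to 16 (without CP-Dox replicate 2), and 13 to 17. The list G2/M and mitosis genes, CP-Dox against Dox, changed direction without CP-Dox replicate 2 (camera adjusted p = 0.144) and kept it in the other alternatives, with 8.69e-05 (without CP-Dox replicate 1) as the lowest adjusted p without 1 array and 2.88e-05 to 0.763 over all alternatives. The cause was not tested.

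The correlation across genes of the responses to the drug forms, 0.501, was 0.563 without the dimmest 40% of genes and 0.398 to 0.567 without 1 array (without Dox replicate 4 and PBS replicate 4). With the PBS arrays split it was 0.167 on average, where the split removes the shared controls. Genes called in both comparisons with PBS numbered 2 with another quantile normalization and 0 to 2 without 1 array, the 2 without CP-Dox replicate 4.

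The replicate numbers were checked for pairing. Of 12 pairs of arrays with the same number, 8 had a correlation over 0.1 of their deviations from the group means (-0.31 to 0.51), and 6 of 12 arrays had their highest correlation outside the group with their own number. No level expected by chance was computed for these counts, so that pairing by replicate number stays undecided. The paired fit (replicate block) gave 995, 0 and 8 genes in the 3 comparisons. The signal over background of the probe sets was not given in the sources used here, so that its limit on the dim genes could not be set.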

Other observations

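The lists and the fits without CP-Dox replicate 2 given here were chosen after the results were seen. Phgdh had the lowest p in both comparisons of CP-Dox, so 12 genes of serine and one-carbon metabolism were collected. In CP-Dox against PBS, 10 fell and 2 rose (median log2 fold change -0.91, limma camera p = 1.72e-06, and 0.00860 with an estimated correlation). The serine synthesis genes Phgdh and Psph were at -1.15 and -0.64 and Psat1 fell as well, the one-carbon genes Shmt1, Shmt2, Mthfd1 and Mthfd2 at -1.10, -1.19, -0.61 and -1.20, and Gart, Ahcy and Gcsh at -0.57, -0.90 and -0.92. Aldh1l1 and Gldc rose by 1.02 and 1.17. Without CP-Dox replicate 2, again 10 fell and 2 rose. In Dox against PBS none passed by limma over all genes (median -0.17, camera p = 0.0653, and 0.230 with an estimated correlation). In CP-Dox against Dox, 2 fell (median -0.67, camera p = 2.58e-07, and 0.00573 with an estimated correlation), and without CP-Dox replicate 2, 8 fell and 1 rose. These p values come from a list chosen on the same data and are not independent evidence.

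A list of 16 erythroid precursor genes was also collected. In Dox against PBS none passed by limma over all genes, with 8 higher and 8 lower (median 0.00, camera p = 0.221, and 0.450 with an estimated correlation). Hbb-b2 and Alas2, at -1.40 and -1.70, had the lowest p of that comparison. The other probe set of Hbb-b2 was at -2.61 and did not pass over all probe sets. The haemoglobin probe sets with several symbols, which are not in this list, were at -3.78 on average. Hemgn, Rhag, Hba-a2, Hba-a1 and Epb42 were dim, with PBS means of 4.52 to 5.26, below the 25th percentile of each PBS array (5.31 or more). The flat median therefore does not exclude an erythroid change. In CP-Dox against PBS, 2 fell, Alas2 by 1.48 and Hbb-b2 by 1.27 (median -0.17, camera p = 0.0370, and 0.211 with an estimated correlation). Without CP-Dox replicate 2 again 2 fell, and the camera p was 0.124. In CP-Dox against Dox none passed (median -0.07, camera p = 0.220, and 0.448 with an estimated correlation), and without CP-Dox replicate 2, 2 fell.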
